A study of Mus musculus with 48 samples.

How the data were processed

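Jejunum, the middle part of the small intestine, was profiled by RNA sequencing in mice kept in constant darkness. The labels give 2 genotypes, a control with floxed Bmal1 alleles (bmal1fl/fl) and a knockout written Bmal1iec-/-, and 6 circadian times (CT1, CT5, CT9, CT13, CT17 and CT21). Bmal1, whose gene symbol is Arntl, encodes a transcription factor at the core of the circadian clock, and in this study its loss is aimed at the cells of the intestinal epithelium, whereas the samples are whole jejunal tissue. The labels describe 48 libraries, 4 per genotype and time. A column matched 47 of them by name, so knockout CT9 has 3 libraries, and the remaining library was not analysed here. Groups were taken from the genotype and time labels, and replicate numbers were given in accession order within a group and pair nothing. The labels do not say that each library came from its own mouse, so p-values measure the spread between these samples.

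The deposited table holds raw read counts per gene, made by the authors from 1 library per column and not scaled. Per the labels' protocols, RNA was purified with a NucleoSpin kit and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and marks its strand. Per the submitters' processing notes, the tools included FastQC 0.11.5, Trimmomatic 0.39, STAR 2.7.5c, SAMtools 1.3.1, featureCounts 1.4.6 and DESeq2 1.22.0, with the mm10 genome. Their settings, the annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Values of genes with near-identical copies (immunoglobulin segments, alpha-defensins, Sprr2a genes, Hspa1a and Hspa1b, H2 genes) and of genes that overlap another gene are therefore uncertain, as reads may have been split between them or dropped.

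The table has 55401 gene IDs, of which 33965 had a count above 0 in any library, and 0 lines that name no gene. Symbols and coordinates came from a GENCODE annotation of the mm10 assembly: 54349 IDs matched with their version, 792 matched with the version ignored and 260 had no match. Total counts ranged from 4.34 to 6.91 M (mega, the SI prefix) per library, with a median of 5.43 M. The floor of 3 counts that an observed 0 allows corresponded to 0.434 to 0.692 counts per M of the library total. Elsewhere CPM is the count of a gene per M counts of the genes kept by the filter, after the scaling of libraries given below. The floors cover counting error only, and reads without molecular identifiers are not independent molecules. Standard errors and bounds from the fits also include the spread between libraries. No libraries agreed within sampling noise: over 1081 pairs the smallest chi-square per degree of freedom was 3.49, and the median over the 69 pairs within a group was 8.44.

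Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with filterByExpr on the 12 groups (minimum count 10, minimum total count 15, smallest group size 3), which left 15646 genes. Libraries were scaled by TMM. A quasi-likelihood model with a mean per group was fitted to all 47 libraries (35 residual degrees of freedom, robust variance estimation), so all groups share 1 estimate of spread. The contrasts were taken on the log2 scale. The first was the mean of the 6 knockout group means minus that of the 6 control group means. The others were knockout minus control at each time. A model with an intercept, a cosine and a sine of 24-h period per genotype (41 residual degrees of freedom) gave F tests of the rhythm in control, of the rhythm in knockout and of the difference between them. Amplitude is the distance from the mid-level to the fitted peak on the log2 scale, and the peak is given in CT hours. A rhythm was called lost or damped when the difference and the control rhythm passed and the knockout amplitude was lower, and gained or enhanced in the mirror case. The test of the difference covers amplitude and peak time together, and amplitude was not tested by itself. All adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test over the 15646 genes, unless another test is named, with a threshold of 0.05. Values per group are means of CPM ± SD. Log2 fold changes are knockout minus control with their standard error (SE), and those of genes with a few counts in a group depend on the prior count of the fit. CPM values that stand for a whole genotype are arithmetic means of its 6 group means. The log2 fold change over all times averages differences on the log2 scale instead. For genes that vary over the day it need not match the ratio of the CPM means.

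The 28 gene lists (392 genes, 26 of them not measured) cover clock, metabolic, transport, defence and stress functions and the markers of other cell types that a piece of jejunum can hold. They were fixed before the data were examined, together with the groups, the tests, the alternatives and the rule for the genes named. That rule takes Arntl first in every group, every measured clock gene, the 10 largest mean changes each way that pass with the same sign at all 6 times, the 5 largest each way at the time with most calls, the 10 largest amplitudes per genotype and the 10 smallest p for a difference in rhythm outside the clock list, all with a mean log2 CPM of at least 1 and a given gene name. It also takes up to 4 members of each list with the smallest p in the comparison at hand, and other list members that are named were chosen after their values were seen. Lists were tested with camera (preset correlation between genes of 0.01, and an estimated correlation beside it) and fry on the genotype mean effect, and with two-sided Fisher's exact tests against all other genes tested for rhythms. Within each of these tests p-values were adjusted over the lists. An adipocyte list was added after the data were seen. Some genes that this rule takes are not reported here.

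The fits were tested on counts simulated with known changes from these libraries' means and totals. For the genotype mean effect, 43.3% of 67 genes changed by a log2 fold change of 0.3 were recovered, 91.0% of 67 at 0.6 and 86.4% of 66 at 1, with 3.92% false calls. For CT9, the time with the smallest group, 28.4% were recovered at 0.6, 64.2% at 1 and 89.4% at 2, with 5.47% false calls. Of the simulated rhythms with an amplitude of 0.3, 0.6 and 1, 32.8%, 77.6% and 98.5% were recovered in control (7.95% false calls) and 46.3%, 95.5% and 97.0% in knockout (4.79% false calls). A difference in rhythm was recovered for 17.9%, 58.2% and 87.9% of the genes with these amplitudes (8.40% false calls), so in the simulation it was missed for most genes with a small rhythm. Simulated counts were drawn for each gene on its own, with few genes changed and without a bias between libraries. These rates need not hold for the real comparisons.

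Alternatives were other scalings (relative log expression and upper quartile), no filter and a stricter filter, another dispersion estimate, DESeq2 1.42.0, limma-voom, a covariate for the range of the numbers in the titles (their meaning is not given in the sources used here), stricter thresholds, an additive model, 6 time levels in place of the harmonic, fits on fewer libraries, and leaving out each library and each time. Added after the data were seen were fits without the libraries that stood apart and fits with a length-bias covariate per library. A library was taken to stand apart when the interquartile range of its relative log expression, the log2 ratio of each gene to its median over libraries, exceeded 1.5 times the median library's range. Chance was examined with other splits of the samples, 35 per time and 100 drawn for the other comparisons.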

Results

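RNA from whole jejunum was sequenced in control mice (floxed Bmal1 alleles) and in knockout mice whose Bmal1 loss is aimed at the intestinal epithelium, at CT1, CT5, CT9, CT13, CT17 and CT21 in constant darkness. CT (circadian time) counts hours of the animals' own cycle in the absence of light. Each group had 4 libraries, except knockout CT9 with 3. Total counts ranged from 4.34 to 6.06 M in the 24 control libraries (median 5.35 M) and from 4.79 to 6.91 M in the 23 knockout libraries (median 5.45 M). By group, the lowest totals were in control CT1 (4.34 to 5.43 M) and control CT21 (4.49 to 5.16 M), and the highest in knockout CT13 (5.44 to 6.91 M). In 5 libraries the genes departed from their median over libraries more widely than elsewhere: control CT21 replicate 1, knockout CT1 replicates 1, 2 and 3, and knockout CT21 replicate 4. The interquartile range of relative log expression was 0.60 to 1.12 in these and at most 0.476 in the others. In the same libraries long genes gave lower values, with a slope of relative log expression on gene length of −0.163 to −0.305 against −0.05 to 0.05 in the others. They differed in other measures. The slope on GC content was 4.0, 5.11 and 5.72 in control CT21 replicate 1, knockout CT1 replicate 3 and knockout CT21 replicate 4, and in knockout CT1 replicates 1 and 2 it lay within the range of the others (−2.01 to 2.19). Mitochondrial genes took 2.42% to 2.86% of counts in the first 3, 5.08% and 7.34% in these 2 and 3.74% to 5.63% elsewhere.

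The first question was whether transcripts of the targeted gene and of the clock differed between the genotypes. Arntl (Bmal1, ENSMUSG00000055116.8) is a protein-coding gene on chromosome 7, positions 113207465 to 113314126, plus strand of mm10, and its counts are summed over exons. In control it stood at 75.5 ± 2.99 CPM at CT1, 30.4 ± 3.72 at CT5, 10.4 ± 1.34 at CT9, 11.5 ± 2.02 at CT13, 47 ± 3.88 at CT17 and 78.4 ± 11.3 at CT21 (SD, n = 4 each). In knockout it stood at 27.3 ± 7.15 CPM at CT1, 31.4 ± 2.33 at CT5, 28.2 ± 3.11 at CT9, 31.2 ± 3.21 at CT13, 30.5 ± 2.39 at CT17 and 30.9 ± 5.38 at CT21 (SD, n = 4 each, 3 at CT9). Single libraries spanned 8.48 to 89.4 CPM in control and 18.4 to 37.0 CPM in knockout. Knockout was lower at CT1 (log2 fold change −1.46, SE 0.14, adjusted p = 9.6e-10), CT17 (−0.62, SE 0.14, 0.0058) and CT21 (−1.34, SE 0.14, 2.0e-08). It was higher at CT9 (1.43, SE 0.16, 1.6e-08) and CT13 (1.43, SE 0.15, 2.8e-09). The mean over times did not pass (−0.09, SE 0.06, edgeR adjusted p = 0.314). The fitted 24-h amplitude was 1.61 (SE 0.07, adjusted p = 8.4e-23) in control, with a peak at CT22.4. In knockout it was 0.04 (SE 0.07, 0.896), and the difference passed (edgeR adjusted p = 2.4e-16). A count over whole genes does not show which exons were present, so the deletion itself was not measured.

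Of the 22 core clock and clock output genes, 6 rose in the knockout in their mean over times, 7 fell and 9 did not pass (6 and 10 adjusted over the list alone). Npas2, a paralog of Clock that can pair with BMAL1, rose from a mean of 41.2 to 85.1 CPM (log2 fold change 1.18, SE 0.06, adjusted p = 1.8e-18). The repressor Cry1 rose from 29.1 to 54.6 CPM (1.07, SE 0.09, 5.1e-13). Cry2 (0.70, SE 0.06, 2.8e-12) and the repressor Nfil3 (0.79, SE 0.10, 1.6e-08) also rose. Nr1d1 (REV-ERBα), a nuclear receptor that represses Arntl, fell from 58.8 to 9.40 CPM (−1.94, SE 0.11, 2.2e-17) and its paralog Nr1d2 from 65.8 to 17.0 CPM (−1.80, SE 0.10, 1.0e-17). The PAR bZIP output factors Dbp (−0.81, SE 0.12, 1.7e-06) and Tef (−0.54, SE 0.05, 2.3e-10) fell, as did Per3 (−1.05, SE 0.09, 1.4e-12), Per1 (−0.61, SE 0.12, 1.7e-04) and the kinase Csnk1e (−0.26, SE 0.06, 8.5e-04). The mean effects of Per2 (0.21, SE 0.11, adjusted p = 0.183), Clock (0.03), Rora (−0.25), Hlf (−0.22), Ciart (−0.50), Bhlhe41 and Csnk1d (0.02) did not pass (edgeR quasi-likelihood, adjusted). Per2 (0.32, adjusted p = 0.0162) and Ciart (−0.70, 0.0333) passed without the 5 libraries named above. Bhlhe40 was higher by 0.17 (adjusted p = 0.031), a call that ended without the 5 libraries named above (0.15, adjusted p = 0.0809) and on leaving out any of 11 single libraries. The list's median (−0.11) and mean (−0.13) were below 0 while camera gave its direction as up, and the set as a whole did not differ from other genes (adjusted p = 0.900).

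Daily patterns of the clock genes also differed between the genotypes. In control 18 of the 22 had a 24-h rhythm and in knockout 11, and the difference passed for 13, each with a lower amplitude in the knockout (18, 14 and 14 adjusted over the list alone). Nr1d1 in control rose from 32.5 ± 5.6 CPM at CT1 to 142 ± 12.5 at CT5 and was at 1.91 ± 0.824 at CT21 (SD, n = 4). In knockout it ran from 2.71 ± 0.481 at CT1 to 21.2 ± 6.35 at CT9 (n = 4 and 3). Its amplitude was 2.96 (SE 0.13, peak CT7.16) in control and 1.93 (SE 0.17, peak CT8.16) in knockout (edgeR adjusted p of the difference 8.8e-04). Dbp at CT9 was 77.2 ± 17.1 CPM in control and 16.1 ± 4.95 in knockout, with amplitudes of 3.17 (SE 0.15) and 1.70 (SE 0.16) and peaks at CT9.53 and CT9.79 (3.2e-05). Rhythms that did not pass in the knockout included Npas2 (amplitude 0.86 in control and 0.08 in knockout, 7.2e-07) and Cry1 (0.95 and 0.08, 4.6e-05). Per2 peaked at CT14.1 in control, where it reached 226 ± 31.2 CPM at CT13 against 122 ± 22.9 in knockout, and its amplitude was 1.88 in control and 0.75 in knockout (4.0e-04). Per1 (1.35 and 1.17, adjusted p = 0.93), Nr1d2 (1.83 and 1.51, 0.471), Ciart (2.72 and 1.61, 0.218) and Bhlhe41 (1.02 and 0.96, 0.998) kept rhythms whose difference did not pass. The share of clock genes exceeded that of other genes tested for the control rhythm, the knockout rhythm and the difference (Fisher's exact test, adjusted p = 5.6e-08, 0.0011 and 3.2e-17). The control rhythm of Csnk1d (0.13, edgeR adjusted p = 0.022) ended on leaving out any of 5 single libraries.

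**Figure D1:**
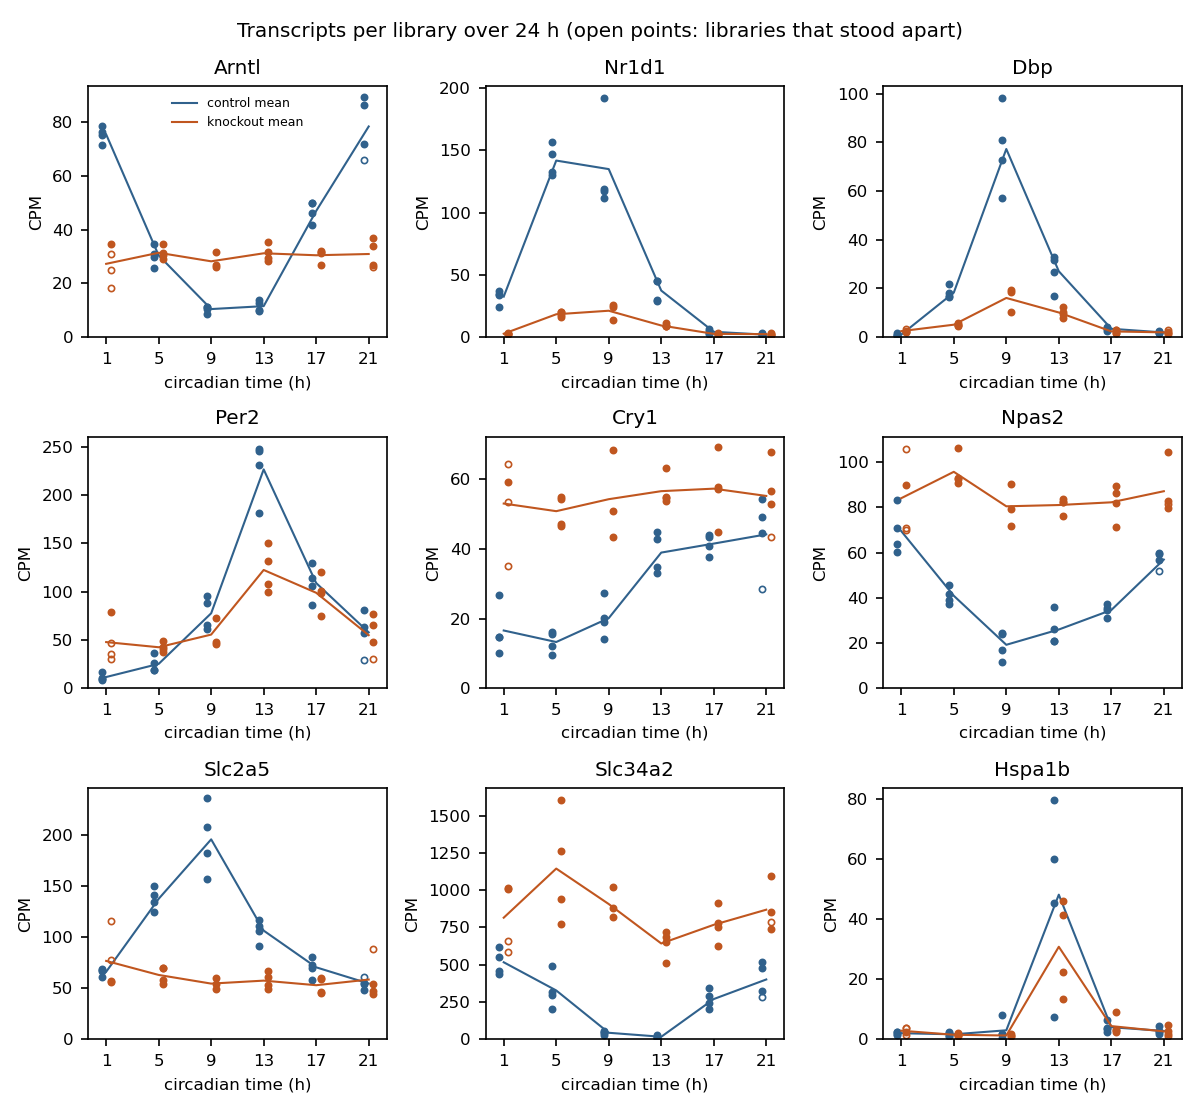
CPM (linear axes from 0) against circadian time in h for 9 genes, with a point per library, lines through the group means, control in blue and knockout in orange, and open points for the 5 libraries that stood apart. Arntl ranged from 8.48 to 89.4 CPM in control and from 18.4 to 37.0 CPM in knockout, and Hspa1b reached its highest group mean at CT13 in both (48 and 30.7 CPM).

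**Figure D2:**
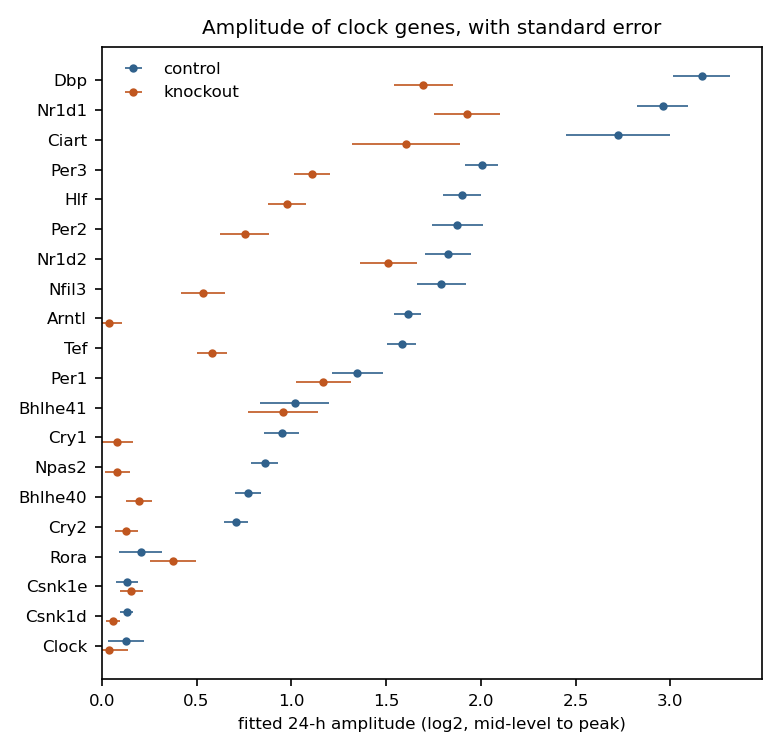
Fitted 24-h amplitude (log2, mid-level to peak, linear axis from 0) of core clock and output genes in control (blue) and knockout (orange), with horizontal bars for the standard error of the fit. Dbp fell from 3.17 to 1.70 and Arntl from 1.61 to 0.04.

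The next comparison took the genotype effect over all times. Slc34a2, a sodium-phosphate cotransporter, rose from 261 to 857 CPM in the knockout (log2 fold change 2.48, SE 0.11, adjusted p = 2.1e-20). Its fold change averages log2 differences over the times and is not the ratio of these CPM means. The succinate receptor Sucnr1 rose from 1.2 to 9.49 CPM (2.93, SE 0.18, 7.4e-19). Slc13a1, a sulfate transporter, fell from 71.6 to 12.5 CPM (−2.08, SE 0.12, 1.3e-16), and Bco1, the enzyme that cleaves beta-carotene to retinal, fell from 90.7 to 5.67 CPM (−3.83, SE 0.23, 2.3e-16). In all, 3694 of 15646 genes passed, 1933 higher and 1761 lower (1599 and 1985 with upper quartile scaling). Of the 3694, 219 were higher and 488 lower by at least 1.5-fold, with a median absolute log2 fold change of 0.30 among those passing. The 10 largest rises with the same sign at all 6 times included the water channel Aqp8 (4.81, SE 0.48), the tight junction gene Cldn8 (3.01, SE 0.27), Adad2 (2.86, SE 0.22), and the amino acid transporter Slc38a8 (2.67, SE 0.23). The rest, besides Slc34a2 and Sucnr1, were the secreted factor Lect2 (2.05, SE 0.19) and the epithelial barrier genes Sprr2a1 (2.50), Sprr2a3 (2.23) and Sprr2a2 (2.08). Aqp8 rose from 1.14 to 20.9 CPM. As control had 3 of its counts in total at CT9 and 2 at CT13, its fitted fold depends on the prior count. The 10 largest falls included the ubiquitin-like modifier Ubd (−3.16, SE 0.51, from 22.3 to 2.50 CPM) and Ceacam10 (−2.51, SE 0.38). Others, besides Bco1 and Slc13a1, were the immunoglobulin genes Ighv1-47 (−3.20, SE 0.69), Ighg1 (−2.49, SE 0.55), Igkv3-4 (−2.49, SE 0.78), Igkv3-10 (−2.33, SE 0.69) and Ighd (−2.27, SE 0.82). These and the Sprr2a genes can share reads with near-identical copies. The call ended for Igkv3-4 without control CT1 replicate 4 and with limma-voom, for Igkv3-10 without control CT5 replicate 2 or control CT17 replicate 3. It ended for Ighd without control CT13 replicate 4 or control CT17 replicate 1. The calls of Igkv3-10 (adjusted p = 0.0546) and Ighd (0.0823) also ended without the 5 libraries named above. All p-values are edgeR quasi-likelihood values adjusted over all genes tested.

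Transcripts of T cells and intraepithelial lymphocytes were lower in the knockout. All 10 measured members of that list fell (10 adjusted over the list alone), with a median log2 fold change of −1.30. The cytotoxic granule genes Gzma, from 108 to 34.7 CPM (−1.61, SE 0.14, adjusted p = 2.7e-11), and Gzmb, from 46.9 to 15 CPM (−1.64, SE 0.15, 3.0e-11), fell. So did the coreceptor Cd8a (−1.38, SE 0.13, 2.1e-11) and the integrin Itgae (−1.21, SE 0.11, 7.4e-12), which holds these cells in the epithelium. Of the 9 genes of MHC class II presentation, 8 fell (8 adjusted over the list alone, median −1.38). Cd74, the invariant chain (−1.45, SE 0.16, 9.7e-09), H2-Ab1 (−1.52, SE 0.15, 1.5e-09) and the transactivator Ciita (−1.38, SE 0.15, 5.5e-09) fell, while Ifi30 (0.12) did not pass (edgeR). Camera with its preset correlation gave adjusted p = 1.6e-22 for the T cell list and 7.9e-16 for MHC class II, and both held with an estimated correlation (0.0048 and 0.0084). Of 10 B and plasma cell genes, 9 fell (9 adjusted over the list alone, median −1.51, camera adjusted p = 5.4e-04, but adjusted p = 0.409 with an estimated correlation). Among them were Jchain, which joins polymeric antibodies (−0.48, SE 0.11, 9.6e-04), and the B cell factor Pax5 (−2.88, SE 1.00, 0.0031). Cr2, Pax5 and Fcer2a had at most 3 counts in total in single knockout groups, so their fitted folds depend on the prior count, and Cr2 lost its call without control CT17 replicate 1. High values of the B cell genes came from a few control libraries. Cr2 stood at 28.2 CPM in control CT9 replicate 1 and 9.44 CPM in control CT13 replicate 4, against at most 2.15 CPM in all other libraries. Of 9 myeloid and mast cell genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.0878). Among them were lysozyme Lyz2 at −0.46 (SE 0.07, 1.4e-06) and the integrin Itgam at 0.34.

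**Figure D3:**
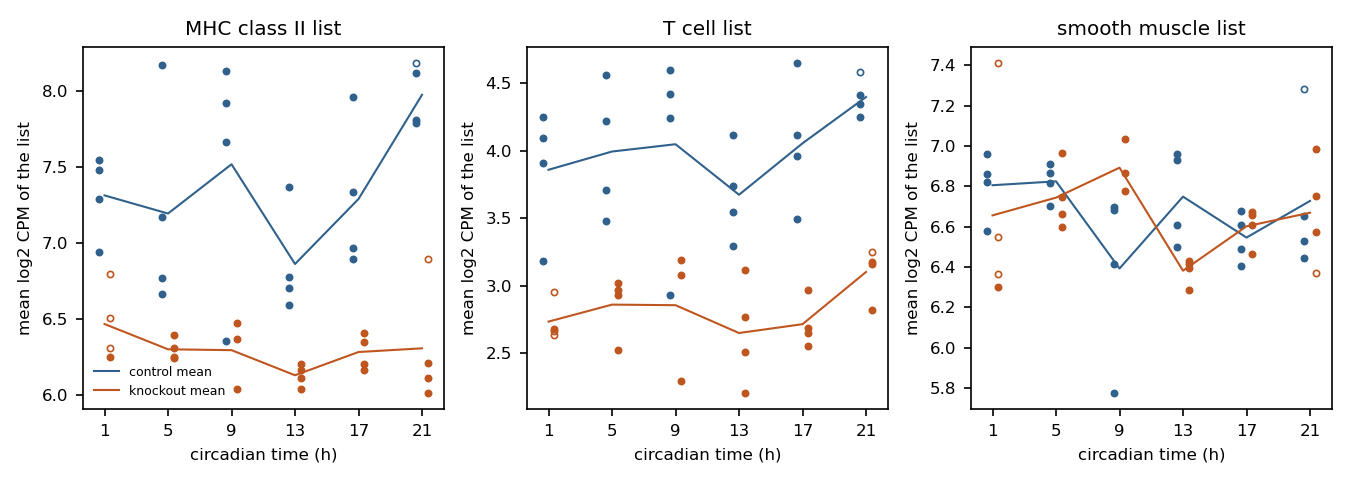
Mean log2 CPM over the members of the MHC class II, T cell and smooth muscle lists (axes do not start at 0) against circadian time in h, with a point per library, lines through the group means, control in blue, knockout in orange and open points for the 5 libraries that stood apart. Median log2 fold changes were −1.38, −1.30 and −0.01.

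Some lists of markers of other cells in a piece of jejunum had no member that passed, over all genes or adjusted over the list alone. These were smooth muscle (10 genes), enteric neurons and glia (9), pancreatic acinar cells (2) and, in a list added after the data were seen, adipocytes (10). Their lowest adjusted p were 0.499 for Synpo2, 0.135 for Sox10, 0.316 for Clps and 0.186 for Cidec (edgeR), and their medians were −0.01, −0.07, 0.03 and −0.01. The acinar gene Cela1 passed without the 5 libraries named above (−0.30, adjusted p = 0.0258). For these lists camera gave adjusted p = 0.900, 0.960 and 0.960 for the first 3 and an unadjusted p = 0.538 for adipocytes. Of 10 fibroblast and endothelial genes, 3 fell (5 adjusted over the list alone), the endothelial receptor Kdr (−0.34, SE 0.07, 3.7e-04) and Pecam1 (−0.20) and the matrix gene Dcn (−0.28, SE 0.07, 0.003). Of 14 enteroendocrine genes, 5 rose (5 adjusted over the list alone), among them the hormone genes Gcg (0.35, SE 0.07, 1.5e-04) and Cck (0.47, SE 0.10, 5.4e-04). Both lists had camera adjusted p = 0.0201, but adjusted p = 0.443 and 0.442 with an estimated correlation. Of 7 tuft cell genes, 3 rose (3 adjusted over the list alone), including the cation channel Trpm5 (0.66, SE 0.09, 1.8e-07), with camera adjusted p = 0.0579. Of 12 Paneth cell genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.197). The alpha-defensins Defa21 (−0.89, SE 0.18, 2.9e-04) and Defa22 (−0.87), which can share reads with copies, were among those that fell. Of 11 goblet cell genes Zg16 passed (0.24, edgeR adjusted p = 0.031) and none did adjusted over the list alone (camera adjusted p = 0.833). That call ended without the 5 libraries named above and on leaving out any of 5 single libraries. Of 10 stem cell genes, 1 rose (Axin2, 0.25, SE 0.05, 8.0e-05) and 1 fell (Prom1, −0.20), the same adjusted over the list alone (camera adjusted p = 0.895). Of 22 cell cycle genes, 2 rose and 5 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.0579). Among them were the kinase Wee1 at −0.34 (SE 0.06, 4.1e-05) and cyclin Ccnd1 at −0.46 (SE 0.08, 2.8e-05).

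Genes of bile acid handling were higher in the knockout: 4 of 6 rose and none fell (5 rose adjusted over the list alone). The median log2 fold change was 0.44 and camera gave adjusted p = 6.4e-04, which held with an estimated correlation (0.0379). The basolateral bile acid exporter subunits Slc51a (from 146 to 231 CPM, 0.69, SE 0.09, adjusted p = 1.9e-07) and Slc51b (0.68, SE 0.12, 3.2e-05) rose. So did the pump Abcc3 (0.52, SE 0.11, 2.4e-04) and the bile acid receptor Nr1h4 (0.37, SE 0.05, 4.1e-07). Of 30 genes of xenobiotic metabolism, 12 rose and 6 fell (12 and 6 adjusted over the list alone). Cyp2c55 went from 119 to 329 CPM (1.88, SE 0.18, 2.4e-10) and the efflux pump Abcg2 was higher by 0.79 (SE 0.04, 3.9e-18). The pump Abcb1a went from 342 to 163 CPM (−0.99, SE 0.11, 1.3e-09) and Por, the electron donor of cytochromes P450, was at −0.58 (SE 0.09, 1.1e-06). Camera gave adjusted p = 0.0201 for that list, but adjusted p = 0.714 with an estimated correlation and 0.169 without the 5 libraries named above. Of 19 genes of fatty acid oxidation and PPARα targets, 8 rose and 2 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.00599, but adjusted p = 0.442 with an estimated correlation). Angptl4, an inhibitor of lipoprotein lipase, went from 38 to 132 CPM (adjusted p = 1.8e-08) and the oxidation enzymes Etfdh (0.38, SE 0.05, 3.0e-08) and Acadm (0.26, SE 0.04, 8.3e-07) rose. Cpt1a, which moves fatty acids into mitochondria, fell by 0.26 on the log2 scale (SE 0.05, 1.9e-04). Of 18 genes of amino acid and peptide transport, 3 rose and 7 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.0201, but adjusted p = 0.463 with an estimated correlation). Those that fell included the peptide transporter Slc15a1, from 726 to 514 CPM (−0.45, SE 0.07, 2.4e-06), and the proton-coupled transporter Slc36a1 (−0.50, SE 0.08, 2.9e-06).

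Genes of nutrient uptake moved both ways. Of 15 genes of sugar digestion and transport, 7 rose and 4 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.468). The glucose-6-phosphatase G6pc went from 88.3 to 142 CPM (0.94, SE 0.10, adjusted p = 7.9e-10), the fructose transporter Slc2a5 from 105 to 60.4 CPM (−0.66). The starch-digesting Mgam (−0.53, SE 0.08, 5.8e-07) and the transporter Slc2a7 (−0.40, SE 0.07, 4.1e-05) fell. Of 24 genes of fat absorption and lipoproteins, 4 rose and 8 fell (6 and 8 adjusted over the list alone). Camera gave its direction as down (adjusted p = 0.468), with a median of 0.00 and a mean of −0.06. The cholesterol exporter Abca1 went from 74.1 to 32.0 CPM (−1.10, SE 0.15, 5.7e-07), the triglyceride-forming Dgat2 from 456 to 291 CPM, and the fatty acid-binding Fabp2 stood at −0.31 (SE 0.07, 0.0014). Without the 5 libraries named above camera passed for 4 lists that did not pass with them: fat absorption (0.0461), cell cycle (0.0135), Paneth cell (0.0118) and myeloid cell (0.0372). With an estimated correlation none of the 4 passed (adjusted p = 0.594 for the first 3 and 0.407 for the last). Of 15 genes of antimicrobial and mucosal defence, 4 rose and 4 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.895). The antimicrobial lectin Reg3a went from 250 to 571 CPM (1.21, SE 0.12, 4.3e-10) and the phospholipase Pla2g5 stood at −1.83 (SE 0.26, 1.6e-07). Of 7 genes of short-chain fatty acid transport and sensing, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.0946). Of 9 genes of iron handling and proximal identity, 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera 0.179), with the ferritin chain Fth1 at 0.56. Without the 5 libraries named above 5 genes of that list passed, among them Onecut2 (0.29, adjusted p = 0.0031). In fatty acid synthesis 4 of 14 fell (4 adjusted over the list alone, camera 0.107), with the desaturase Scd2 at −0.55. The mean log2 CPM of these genes was highest in control CT13 replicate 2 (6.99), where that of the adipocyte list was also highest (6.63). It was lowest in control CT9 replicate 4 (4.68, adipocyte list 0.752). Whether fat in single samples contributed to these falls was not tested. Of 21 genes of cholesterol synthesis 1 rose and 4 fell (1 and 4 adjusted over the list alone, camera 0.411), and of 9 glucocorticoid-responsive genes 1 rose and 1 fell (2 and 2 adjusted over the list alone, camera 0.639). None of 12 heat shock and temperature genes passed, over all genes or adjusted over the list alone, with the lowest adjusted p for Hspa8 (0.161). That list's median was 0.01 and its mean −0.03 (camera 0.895, upward). All p-values of single genes are adjusted edgeR values.

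At single times the question was when in the cycle the genotypes differed. At CT1, the time with most calls, Nr1d1 fell by 3.56 on the log2 scale (SE 0.28, adjusted p = 1.3e-13) and Nr1d2 by 2.67 (SE 0.30, 3.3e-08). Cry1 (1.69) and Per2 (2.07, SE 0.30, 2.5e-05) rose. These 4 calls held without the 5 libraries that stood apart. Of 15 sugar genes 8 rose and none fell, where 12.8% of all genes tested rose, and without the 5 libraries 2 of the 15 and 0.146% of all genes rose, with a list median of 0.41 (0.69 before). In all 3287 genes passed, 1998 higher and 1289 lower. Among the 5 largest changes each way were Aqp8 (3.77, SE 0.50, 1.5e-07), Sucnr1 (2.95), Adad2 (2.88) and the skeletal muscle actin Acta1 (3.14, SE 0.58, 1.4e-04). Acta1 stood at 1.38 ± 0.371 CPM in control and 12.3 ± 5.59 in knockout (SD, n = 4). The others, besides Nr1d1 and Nr1d2, were the noncoding RNA Carmn (−2.49, 0.0076) and the immunoglobulin segments Igkv9-124 (3.19, 0.0335), Ighv8-5 (−4.53, 0.0256) and Ighv1-47 (−4.13, 0.0245). With upper quartile scaling 50.7% of the genes called at CT1 were higher, against 60.8% with TMM. Of the 4 knockout CT1 libraries, 3 stood apart from the other libraries. Without these and the 2 others that stood apart 38 genes passed at CT1, 32 of them among the 3287, and Acta1 (then 2.54), Carmn (−2.64), Igkv9-124 (0.90), Ighv8-5 (−3.35) and Ighv1-47 (−3.20) no longer passed, with 1 knockout library left at that time. The count was 1535 without control CT1 replicate 1 and 1351 without knockout CT1 replicate 1. By the numbers in the titles, all 4 control CT1 libraries were in the higher range and knockout CT1 replicates 1 and 2 in the lower. With the range as a covariate 2699 genes passed at CT1. Calls of the 3 segments also ended without single libraries of CT1, where Ighv8-5 turned to 0.36 without control CT1 replicate 2. All adjusted p-values are from edgeR.

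At CT9 and CT13 genes of the mean effect were again among those that differed. At CT9, Slc34a2 was at 42.3 ± 11.0 CPM in control and 906 ± 103 in knockout (SD, n = 4 and 3; log2 fold change 4.42, SE 0.29, edgeR adjusted p = 1.5e-13). Slc2a5 was at 196 ± 34.0 and 54.4 ± 5.08 CPM (−1.85, SE 0.19, 4.9e-09) and Nr1d1 at 135 ± 38.2 and 21.2 ± 6.35 CPM (−2.66). At CT13, Slc34a2 was at 15.5 ± 8.97 and 642 ± 92.7 CPM (n = 4 each; 5.38, SE 0.29, 1.6e-15) and Bco1 at 195 ± 18.7 and 2.30 ± 1.18 CPM (−6.35, SE 0.61, 2.2e-10). At CT9, 627 genes passed (249 higher, 378 lower), and at CT13, 544 (323 higher, 221 lower). Both were called in the same direction for 273 genes and in opposite directions for none, where independent lists would share 10.5 in the same direction, and the times have no library in common. T cell genes fell at both times (7 and 4 of 10) and MHC class II genes at CT9 (7 of 9). At CT13 H2-Ab1 stood at 262 ± 92.9 and 122 ± 8.92 CPM without passing (−1.11, adjusted p = 0.11). The CT9 count was 321 without control CT9 replicate 1, 347 without knockout CT9 replicate 3 and 286 without knockout CT9 replicate 4, and the CT13 count was 340 without control CT13 replicate 2. Without the 5 libraries that stood apart, none of which is from these times, the counts were 1080 at CT9 and 1187 at CT13. Numbers in the titles, whose meaning is not given in the sources used here, fall in 2 ranges, with all 4 control CT13 libraries in the lower and 3 of 4 knockout ones in the higher, and with the range as a covariate 346 genes passed at CT13. Of 35 splits of the CT9 libraries into groups of the same sizes, 2 gave at least 627 genes, the real one included.

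At CT17, CT21 and CT5 fewer genes passed. At CT17, Slc13a1 was at 122 ± 30.3 CPM in control and 10.7 ± 2.0 in knockout (SD, n = 4; −3.52, SE 0.29, edgeR adjusted p = 1.2e-10). Sult6b2, of the sulfotransferase family, was at 61.3 ± 22.8 and 4.92 ± 2.73 CPM (−3.65, SE 0.42, 1.1e-07). At CT21, H2-Ab1 was at 692 ± 138 and 167 ± 80.5 CPM (−2.05, adjusted p = 0.0015) and Gzmb was at −1.74. At CT5, Slc2a5 was at 138 ± 11.0 and 62.9 ± 8.06 CPM (−1.13, 5.5e-05) and Nfil3 was higher by 2.18. The counts were 349 at CT17 (112 higher, 237 lower), 227 at CT21 (107 and 120) and 141 at CT5 (83 and 58). The CT17 count was 225, 201, 209 and 213 without control CT17 replicate 3 and knockout CT17 replicates 2, 3 and 4. The CT21 count was 370 and 133 without control CT21 replicates 1 and 3. The CT5 count was 78, 86, 84, 75 and 79 without control CT5 replicates 1 and 4 and knockout CT5 replicates 1, 2 and 4. Without the 5 libraries that stood apart 854 genes passed at CT17, 293 at CT21 and 298 at CT5. At CT21, 13 of 35 splits of the libraries gave at least 227 genes, the real one included. Counts at single times depend on the power of each contrast, and whether effects differ between times was tested only through the difference in rhythm. T cell genes fell at every time (7, 7, 7, 4, 8 and 7 of 10 from CT1 to CT21, with medians of −1.27, −1.35, −1.33, −1.14, −1.47 and −1.41). In all 29 genes passed at all 6 times, among them Aqp8, Cldn8, Sucnr1, Gzma, Gzmb, Cd8a, Itgae and the efflux pump Abcg2.

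**Figure D4:**
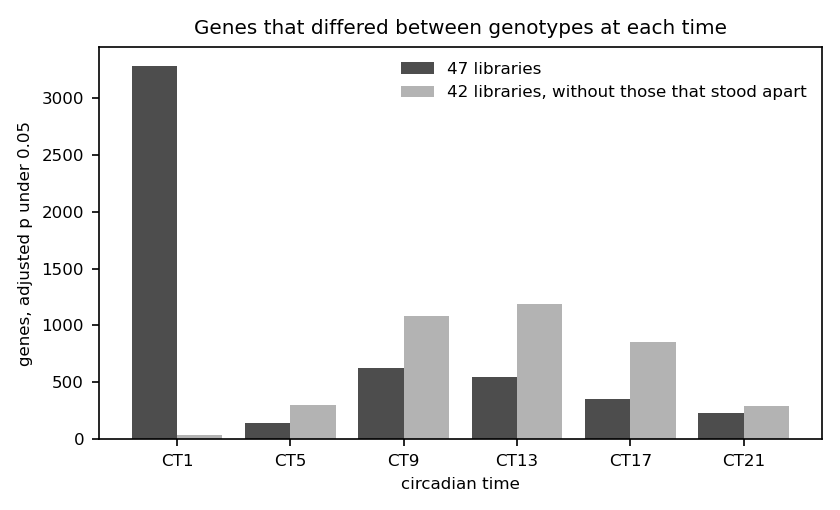
Number of genes with an adjusted p under 0.05 between genotypes at each circadian time (bars from 0), with all 47 libraries in dark grey and with the 42 left after removing those that stood apart in light grey. The CT1 bar went from 3287 to 38 and the CT13 bar from 544 to 1187.

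The next question was which transcripts had a 24-h rhythm in control jejunum. Sult6b2 swung from 1.46 ± 0.694 CPM at CT1 to 117 ± 14.1 at CT13 (SD, n = 4; amplitude 3.18, SE 0.22, peak CT13.9, edgeR adjusted p = 2.3e-16). Dbp and Nr1d1 followed (3.17 and 2.96), and Slc34a2 peaked at CT23.4 (2.27, SE 0.20). Among the 10 largest amplitudes, the inducible chaperones Hspa1b (2.67, SE 0.52, peak CT13.4) and Hspa1a (2.28), which can share reads, and Zbtb16 (2.64, peak CT12.8), a transcription factor induced by glucocorticoids, peaked near CT13. The other 3 of these were Ciart (2.72), Ighd (2.49) and Ighv14-1 (2.24, adjusted p = 0.0367). Those of Ighd without control CT9 replicate 1 and of Ighv14-1 without any of 11 single libraries did not pass. In all, 3301 genes (21.1%) were rhythmic, with peaks spread over the day, from 13.4% in CT4 to CT8 and in CT20 to CT24 up to 22.3% in CT12 to CT16. Time was not balanced over the ranges of the numbers in the titles. In control, CT9 and CT13 libraries were all in the lower range, CT1, CT5 and CT21 libraries all in the higher and CT17 libraries in both. The rhythm test alone does not separate time from range. With the range as a covariate 2731 genes were rhythmic in control and 2640 in knockout. All 12 heat shock and temperature genes were rhythmic (12 adjusted over the list alone, Fisher's exact test adjusted p = 1.1e-07). So were 15 of 18 amino acid and peptide transport genes (15 adjusted over the list alone, 2.8e-07) and 15 of 22 cell cycle genes (21 adjusted over the list alone, 1.8e-05). The share was also above that of other genes for 14 of 24 fat genes (15 adjusted over the list alone, 4.2e-04), 16 of 30 xenobiotic genes (20 adjusted over the list alone, 4.7e-04) and 10 of 15 sugar genes (10 adjusted over the list alone, 7.2e-04). The peptide transporter Slc15a1 peaked at CT9.47 (amplitude 0.60), the fructose transporter Slc2a5 at CT8.66 (0.90), Dgat2 at CT13.5 (1.17) and Wee1 at CT14 (0.69). Of 6 bile acid genes 5 were rhythmic (5 adjusted over the list alone, 0.0072), and of 9 glucocorticoid-responsive genes 6 (6 adjusted over the list alone, 0.0127, led by Fkbp5, 2.08 at CT14.1). Of 10 B and plasma cell genes 6 were rhythmic (7 adjusted over the list alone, 0.0234), a count that was 1 without control CT9 replicate 1.

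For the remaining lists the share of control rhythms did not differ from that of other genes at the threshold of the test. Rhythms passed for 8 of 19 genes of fatty acid oxidation (12 adjusted over the list alone, Fisher's exact test adjusted p = 0.099), 5 of 9 of iron handling (5 adjusted over the list alone, 0.0623) and 7 of 21 of cholesterol synthesis (8 adjusted over the list alone, 0.298). For fatty acid synthesis they passed for 4 of 14 (6 adjusted over the list alone, 0.597), for short-chain fatty acid transport for 3 of 7 (3 adjusted over the list alone, 0.293) and for stem cells for 4 of 10 (4 adjusted over the list alone, 0.328). They passed for 3 of 15 mucosal defence genes (5 adjusted over the list alone), 3 of 10 fibroblast and endothelial genes (4 adjusted over the list alone) and 2 of 14 enteroendocrine genes (2 adjusted over the list alone). They passed also for 2 of 9 myeloid genes (2 adjusted over the list alone) and 1 of 12 Paneth cell genes (1 adjusted over the list alone). No T cell, MHC class II, smooth muscle, neuronal, goblet, tuft or acinar gene passed over all genes or adjusted over the list alone. For 6 of these lists the lowest adjusted p were 0.229 (Gzma), 0.193 (H2-Eb1), 0.0851 (Acta2), 0.087 (Agr2), 0.0822 (Trpm5) and 0.416 (Cela1) by edgeR. Agr2 (0.0432) and Trpm5 (0.0211) passed without the 5 libraries that stood apart. Of 10 adipocyte genes 2 passed (2 adjusted over the list alone).

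In the knockout the same question was asked of its 23 libraries. The chaperone Hspa1b rose from 1.19 ± 0.512 CPM at CT9 to 30.7 ± 15.4 at CT13 (SD, n = 3 and 4; amplitude 2.08, edgeR adjusted p = 0.0024). Hspa1a (2.78, 5.8e-05), Zbtb16 (2.20, 3.3e-04) and Nr1d1 (1.93) were among the 10 largest amplitudes. The rest of these were the immunoglobulin segments Ighv1-77 (3.08, SE 0.82, adjusted p = 0.0022), Igkv1-122 (2.10), Ighv9-1 (2.05), Ighv1-20 and Ighv1-52 (1.98) and the phospholipase Pla2g4c (1.86, adjusted p = 0.0061). Each of these calls ended without 1 library: knockout CT5 replicate 4 for Ighv1-77 and Pla2g4c, CT21 replicate 4 for Igkv1-122, CT13 replicate 3 for Ighv9-1, CT9 replicate 3 for Ighv1-20 and CT17 replicate 1 for Ighv1-52. In all 2340 genes (15%) were rhythmic, and 1139 were rhythmic in both genotypes. Of the peaks, 35.5% (831 genes) lay in CT20 to CT24, a share of 8.05% without the 5 libraries that stood apart, where 27.4% lay in CT16 to CT20 and 22.9% in CT4 to CT8. The number of rhythmic genes was 1788 without these libraries, with 1169 of the 2340 among them, and 3666 without knockout CT21 replicate 1. It was 921 in a fit of knockout libraries alone and 1444 with the length slope as a covariate. The rhythmic share exceeded that of other genes for heat shock and temperature (9 of 12, 10 adjusted over the list alone, Fisher's exact test adjusted p = 1.2e-04) and fat absorption (13 of 24, 14 adjusted over the list alone, 1.2e-04). It also did for glucocorticoid-responsive genes (6 of 9, 7 adjusted over the list alone, 0.0043) and xenobiotic metabolism (11 of 30, 12 adjusted over the list alone, 0.0159). The same held for sugar (7 of 15, 11 adjusted over the list alone, 0.0165), bile acids (4 of 6, 6 adjusted over the list alone, 0.0232) and amino acid transport (7 of 18, 9 adjusted over the list alone, 0.0406). Of the cell cycle genes 7 of 22 were rhythmic (8 adjusted over the list alone, 0.113). Of fatty acid oxidation 6 of 19 (6 adjusted over the list alone, 0.148) and of cholesterol synthesis 3 of 21 (4 adjusted over the list alone, 1). Apart from the clock, the other lists had at most 3 members that passed and at most 4 adjusted over the list alone.

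The test of the difference in rhythm asked where the daily pattern itself changed. Outside the clock, Nat8f5, of the N-acetyltransferase family, ran from 12.5 ± 2.82 CPM at CT1 to 73.9 ± 6.52 at CT13 in control (SD, n = 4). In knockout its group means lay between 10.6 ± 3.0 and 17.2 ± 6.47 CPM (amplitude 1.39 and 0.23, edgeR adjusted p of the difference 1.2e-10). The carboxylesterase Ces1d (1.53 and 0.20, 1.1e-07), Sult6b2 (3.18 and 0.66, 7.0e-07) and Slc13a1 (1.74 and 0.28, 3.7e-07) also peaked in the second part of the cycle in control, at CT17, CT13.9 and CT14.1. Dab1, an adaptor of reelin signalling (1.13 and 0.07, 7.5e-09), the pantetheinase Vnn1 (0.92 and 0.15, 1.4e-07) and the anion transporter Slc17a4 (1.10 and 0.32, 9.3e-07) peaked near CT0 in control. Slc34a2 differed likewise (2.27 and 0.28, 7.1e-05). The rest of the 10 smallest p were Slc2a5 (0.90 and 0.20, 1.5e-07), the ephrin receptor Epha1 (0.60 and 0.06, 3.7e-07) and Aagab (0.57 and 0.14, 7.2e-07). In all 246 genes passed, of which 229 were called lost or damped and 16 gained or enhanced in the knockout. As the test covers amplitude and peak time together, these calls can include genes whose peak moved. Of those called lost or damped, 164 had no rhythm that passed in the knockout. With the range of the numbers in the titles as a covariate 194 genes passed. That range was not balanced over the times in either genotype, so the difference is not fully separated from it. The number gained was 38 without control CT21 replicate 1, 39 without knockout CT21 replicate 1 and 25 without knockout CT21 replicate 2. The fitted amplitude was lower in the knockout for 2844 (86.2%) of the 3301 genes rhythmic in control (median 0.33 and 0.21), in part because these genes were chosen on the control. Of the 2340 genes rhythmic in knockout it was lower for 706 (30.2%), with medians of 0.23 in control and 0.31 in knockout. Among the 1139 genes rhythmic in both, 61.9% had a lower amplitude and the peak was later in the knockout by a median of 0.93 h (quartiles −0.08 and 2.18 h), with 977 (85.8%) within 3 h.

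Sugar genes stood out in this test: 6 of 15 differed (9 adjusted over the list alone, Fisher's exact test adjusted p = 8.8e-07). Besides Slc2a5, the glucose transporters Slc5a1 (amplitude 0.84 in control and 0.30 in knockout, edgeR adjusted p = 1.5e-04) and Slc2a2 (0.94 and 0.30, 0.0398) and the transporter Slc2a7 (1.12 and 0.32, 2.1e-06) had lower amplitudes in the knockout. The mean effects of Slc5a1 (−0.08) and Slc2a2 (0.11) did not pass. Of the fat genes 4 of 24 differed (10 adjusted over the list alone, 0.0046). Dgat2 (1.17 and 0.43, 1.9e-04) and Fabp2 (0.53 and 0.29, 0.0043) were damped, and the peak of the acyl-CoA synthetase Acsl5 was at CT15.1 in control and CT21.2 in knockout (7.8e-06). The call of Fabp1 (0.27 and 0.38, 0.016) ended without knockout CT1 replicate 1 and turned direction without the 5 libraries that stood apart. Differences passed for 3 of 30 xenobiotic genes (8 adjusted over the list alone, 0.0798), among them Abcb1a (1.13 and 0.84, 1.1e-04) and Por (0.73 and 0.07, 8.9e-04). They passed for 2 of 18 amino acid transport genes (8 adjusted over the list alone, 0.179), where the call of Slc7a7 (0.024) ended without any of 3 single libraries and that of Slc3a1 (0.046) without any of 43. They also passed for 1 of 6 bile acid genes (1 adjusted over the list alone, 0.423) and for 1 of 22 cell cycle genes, Wee1 (0.69 and 0.12, 2.7e-05; 1 adjusted over the list alone, 1). In the other lists no member passed over all genes, with lowest adjusted p from 0.0515 for Slc16a3 to 0.891 for Gzmb. Slc25a20 of fatty acid oxidation (edgeR adjusted p = 0.0115) and Slc11a2 of iron handling (0.0424) passed without the 5 libraries that stood apart. Adjusted over the list alone, 2 heat shock, 3 cholesterol synthesis and 1 short-chain fatty acid gene passed. Hspa1b (2.67 and 2.08, adjusted p = 0.936), Hspa1a (0.964), Zbtb16 (0.956) and Fkbp5 (2.08 and 1.68) kept amplitudes whose difference did not pass.

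The last comparison asked whether the genotype effect was limited to rhythmic genes. Of the 3694 genes that passed the mean effect, among them Gzma and H2-Ab1, whose control rhythm did not pass, 2134 (57.8%) passed none of the tests of rhythm in control, rhythm in knockout and difference in rhythm. Not passing does not exclude a small rhythm. Of the same 3694 genes 31.2% were rhythmic in control, like Slc34a2, Slc13a1 and Bco1, against 18.0% of the other genes tested (odds ratio 2.07, Fisher's exact test across genes, which are not independent replicates, p = 6.92e-63). Genes were not matched in expression level or spread, on which the power of both tests depends. The odds ratio therefore does not by itself show a link between genotype effect and rhythm. At an unadjusted p for rhythm 1331 of the genes passed none of the 3 tests.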

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

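The tests of a bias shared by the libraries that stood apart, of a larger effect at CT1, of the clock rhythms, of the stromal markers, of the numbers in the titles and of the CT9 and CT21 genes called at other times were chosen after their results were seen, and those of the follicle genes and of other splits of the samples before.

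Far more genes passed between genotypes at CT1 (3287) than at any other time. A bias shared by the libraries that stood apart is a candidate cause: of the genes called at CT1, 85.6% deviated the same way in control CT21 replicate 1 from the rest of its group, a control library of another time, and 88.3% did in knockout CT21 replicate 4, while the other 37 libraries of other times gave 12.8% to 77.5%. A genotype effect that is itself larger at CT1 stays open, because the 1 knockout library of CT1 that did not stand apart gave 38 genes, and 18 single knockout libraries of other times gave 23 to 794, with 2 of them below 38. Lower values of long genes were common to these libraries, which differed in GC slope (−1.16 to 5.72). The mean log2 CPM of the acinar list was 5.50 in control CT21 replicate 1, 5.56 and 5.67 in knockout CT1 replicates 2 and 3 and 5.79 in knockout CT21 replicate 4. All other libraries had at most 5.16, with 4.82 in knockout CT1 replicate 1. With the length slope as a covariate CT1 had 1357 genes, CT13 1036, CT17 945 and CT9 933, while with libraries of each time alone CT1 had 1075 and CT13 1115. The signs of bias were found on the same data, so both the technical and the biological account are hypotheses.

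Rhythms of clock genes that remained in the knockout, such as that of Nr1d1, can be set against the targeted gene itself. If epithelial cells that kept an intact Bmal1 were the only source, Arntl and its targets would be kept alike, a premise that was not tested. The fitted range of Arntl in the knockout was at most 8.21% of control (upper 95% bound). The range that 7 output genes (Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per3 and Ciart) kept was 10.9% to 36.0%, estimates without intervals. Without the libraries that stood apart the values were 10.86% at most for Arntl and 11.48% to 35.5%. That bound used the standard error of the fit to all libraries, scaled to fewer libraries. Under the premise the values argue against such cells as the only source, by a small margin for the lowest gene. A part from such cells stays open. Clocks in cells other than the epithelium stay open: Arntl itself kept 1.87% of its control range, but how much Arntl such cells hold is not known. A hypothesis of daily cues from outside the epithelial clock also stays open: the 18 heat shock and glucocorticoid-responsive genes rhythmic in control kept a median of 67.8% of their amplitude, within the 36.8% to 72.5% that 95% of random sets of other rhythmic genes with matched amplitude kept, and above it without the libraries that stood apart (75.7% in 19 genes, 35.6% to 73.3% in the sets).

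The lower T cell and MHC class II transcripts of the knockout held in the tests of technical accounts that were made. A smaller non-epithelial share of the samples is argued against by 29 smooth muscle, fibroblast, endothelial, neuronal and glial markers, whose median log2 fold change was −0.076 (quartiles −0.15 and 0.00, range −0.34 to 0.35) where the T cell list had −1.30. Lymphoid follicles in some control samples are argued against as the whole cause, since with a score of 5 follicle B cell genes as a covariate the median of the T cell list was −1.20 with 9 of 10 genes passing, and that of MHC class II −1.14 with 8 genes lower. The numbers in the titles, whose meaning is not given, fall in 2 ranges, and the T cell score was lower in knockout by −1.16 (SE 0.21, 8 against 10 libraries) in the lower range and by −1.21 (SE 0.14, 15 against 14) in the higher range, with −0.98 and −1.12 for MHC class II. Fewer such cells, fewer transcripts per cell, and differences of cage, litter or microbiota between the genotypes stay open and were not tested.

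Other splits of the samples were counted for each comparison, the real one included. Chance could be excluded for the genotype mean effect (3694 genes, highest other 6), the control rhythm (3301, highest other 21) and the difference in rhythm (246, highest other 93). In each, only the real split among 100 was as large. For the knockout rhythm (2340) the real split was also the only one as large, but another gave 2046. As 1169 of the 2340 were called without the libraries that stood apart, the splits do not separate that rhythm from those libraries. None of these splits kept to the ranges of the numbers in the titles, which are not balanced over the times. At CT1 (3287, highest other 1459), CT5 (141, highest other 3), CT13 (544, highest other 3) and CT17 (349, highest other 16) 1 of 35 splits was as large. That is the smallest share that 35 splits can give, and it was not adjusted over the times. The CT1 split with 1459 genes kept together the 3 knockout libraries that stood apart. For CT1 the splits therefore do not separate genotype from those libraries. By the number of genes chance could not be excluded for CT9, where 2 of 35 splits were as large (627, highest other 710), nor for CT21, where 13 of 35 were (227, highest other 3500). The CT9 split with 710 genes differed from the real one only in placing control CT9 replicate 4 with the knockout. Genes also called in the same direction at another time, CT1 left out, numbered 357 at CT9 (highest other 307) and 174 at CT21 (highest other 164). At each of these times 1 gene was shared in the opposite direction. Only 1 of 35 splits, the real one, was as large, again the smallest share possible, and the margins were small. The CT21 split with 3500 genes put control CT21 replicate 1 and knockout CT21 replicate 4, which both stood apart, on the same side, which points to a structure of the samples other than genotype.

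Single libraries far from the rest of their group were looked for on 8 measures in 11 groups of 4 libraries with Dixon's test, and 7 of the 88 tests found 1, where chance gives about 1 in 20. Control CT17 replicate 1 had a total of 5.92 M counts, and the rest of its group had 4.95 to 4.98 M. Mitochondrial genes took 4.12% of counts in knockout CT17 replicate 4 (the others 4.67% to 4.78%) and 2.42% in knockout CT21 replicate 4 (the others 5.19% to 5.45%). The interquartile range of relative log expression was 0.896 in control CT21 replicate 1 (the others 0.317 to 0.371) and 1.12 in knockout CT21 replicate 4 (the others 0.298 to 0.391). Arntl stood at 26.9 CPM in knockout CT17 replicate 4 (the others 31.4 to 31.9). The mean log2 CPM of the T cell list was 2.96 in knockout CT1 replicate 1 (the others 2.64 to 2.68). A difference between the genotypes in the daily pattern itself was found for 246 genes by the test of that difference.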

How the results depend on the processing

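The fits without the libraries that stood apart and with a length-bias covariate were chosen after the data were seen, and the other alternatives before. The fit with RLE size factors or upper quartile scaling, another dispersion estimate, DESeq2 or limma-voom left the counts of genes per comparison within 1.5 times of those reported, except for rhythms gained in the knockout, which numbered 16 as reported, 30 with DESeq2 and 9 with limma-voom. Counts within single lists moved further than that in 2 cases with RLE, 1 with upper quartile scaling, 8 with DESeq2 and 4 with limma-voom. Without a filter on low counts 89 genes passed at CT5, 214 at CT17 and 1496 for the knockout rhythm, and 8 rhythms were gained. With the range of the numbers in the titles as a covariate 346 genes passed at CT13 and 9 rhythms were gained. With fewer libraries in the fit, 921 genes passed for the knockout rhythm in knockout libraries alone, and 1075 at CT1, 394 at CT9, 1115 at CT13 and 58 at CT21 in libraries of that time alone. Without the libraries that stood apart the counts were 38 at CT1, 298 at CT5, 1080 at CT9, 1187 at CT13 and 854 at CT17, and of the 3694 genes of the mean effect 2897 were also among the 3562 called then, of the 2340 of the knockout rhythm 1169 and of the 246 of the difference in rhythm 182. With the length slope as a covariate the counts were 1357 at CT1, 267 at CT5, 1036 at CT13, 945 at CT17, 425 at CT21 and 1444 for the knockout rhythm. At an adjusted p under 0.01, 2336 genes passed for the mean effect, 1230 at CT1, 69 at CT5, 307 at CT9, 291 at CT13, 150 at CT17, 107 at CT21, 1878 for the control rhythm, 729 for the knockout rhythm and 125 for their difference. With at least 1.5-fold 707 passed for the mean effect and 1943 at CT1, with an amplitude of at least 0.3 1870 passed in control and 1247 in knockout, and at an unadjusted p for rhythm 1331 genes had a mean effect and no rhythm. Leaving out each library in turn gave 3399 to 4387 genes for the mean effect, 1351 to 4595 at CT1, 75 to 162 at CT5, 286 to 807 at CT9, 340 to 686 at CT13, 201 to 4.5e+02 at CT17, 133 to 370 at CT21, 2859 to 3685 for the control rhythm, 1751 to 3666 for the knockout rhythm, 193 to 311 for the difference, 181 to 270 lost, 11 to 39 gained and 1967 to 2439 with a mean effect and no rhythm. Of the named genes' values 20330 kept their direction and side of the threshold when a library was left out, 129 came to pass, 161 no longer passed and 1 turned (Ighv8-5, genotype effect at CT1, −5.55 to 0.36). The change in amplitude of Fabp1 turned to −0.058 without the libraries that stood apart and to −0.048 with the length covariate. With fry in place of camera 22 lists kept their side of the threshold. Short-chain fatty acid transport (fry adjusted p = 1.6e-04), iron handling (2.4e-04), myeloid cell (0.0014), tuft cell (0.0016) and cell cycle (0.0206) came to pass. Xenobiotic metabolism (0.0505) no longer passed. Apart from stricter thresholds and smaller sets of libraries, the cause was not tested. No paired analysis was possible because replicate numbers follow accession order and pair nothing. Depth limited the fold changes of Cr2, Pax5 and Fcer2a, which had at most 3 counts in total in single knockout groups. At CT9, with 4 and 3 libraries, 28.4% of simulated log2 fold changes of 0.6 were recovered, and whether depth or the number of libraries set this was not tested.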

Other observations

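Of the tests here, that of the relation between MHC class II and T cell transcripts was chosen after its result was seen, and the adipocyte list was added after the data were seen.

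Genes of defence and of mineral and acid handling moved both ways in the knockout. Pigr, which carries antibodies across the epithelium, rose from 4037 to 5334 CPM (log2 fold change 0.42, SE 0.06, edgeR adjusted p = 1.4e-06). Lypd8, which keeps bacteria from the mucosa, fell from 1615 to 1118 CPM (−0.54, SE 0.07, 8.0e-08) and the hydrogen peroxide-forming Duox2 from 41 to 22 CPM (−1.21, SE 0.33, 0.006). The iron store Fth1 rose from 1457 to 2160 CPM (0.56, SE 0.07, 3.4e-08) and the iron importer Slc11a2 by 0.22 (SE 0.04), while the iron reductase Cybrd1 fell by 0.38 on the log2 scale (SE 0.08). The lactate and short-chain fatty acid transporter Slc16a1 (0.30) rose with its chaperone Bsg (0.28), and Slc5a12, a sodium-coupled transporter of the same acids, fell from 208 to 136 CPM (−0.62, SE 0.17, 0.0079). Of the enzymes and regulators of cholesterol synthesis, Dhcr7 rose (0.22, SE 0.04, 2.1e-04).

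MHC class II transcripts varied between control libraries of the same time, and a hypothesis is that they follow the T cell transcripts. Within control groups the mean log2 CPM of both lists, each taken against its group mean, correlated with Pearson's r = 0.917 and Spearman's rho = 0.912 (n = 24, permutation p = 4e-05 for both). Without the 2 libraries farthest from the median r was 0.879 and rho 0.799 (n = 22, permutation p = 1e-04 and 6.4e-04). Within knockout groups r was 0.289 and rho 0.320 (n = 23, permutation p = 0.2 and 0.18), and the difference between the genotypes was not tested. The 3 relations computed had adjusted p of 1.2e-04, 1.5e-04 and 0.2 for r. The relation in control is in line with shared variation of these cells or of a signal between them and the epithelium, which whole tissue does not separate.

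Markers of fat and of lymphoid follicles marked single samples. The mean log2 CPM of 10 adipocyte genes ranged from 0.609 in control CT9 replicate 1 to 6.63 in control CT13 replicate 2. The median log2 fold change of the list between genotypes was −1.97 at CT13, −1.27 at CT5, 1.18 at CT9 and 1.06 at CT21. A score of 5 follicle B cell genes was 5.10 in control CT9 replicate 1, 3.63 in control CT13 replicate 4, 1.29 in control CT17 replicate 1 and 1.27 in control CT21 replicate 3, and lay between −1.18 and −0.19 in the 23 knockout libraries.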
